A study of Drosophila melanogaster with 4 samples.

How the data were processed

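The study measured where Notch tagged with green fluorescent protein (GFP) sits on chromatin of whole *Drosophila melanogaster* larvae at the wandering stage (L3), by chromatin immunoprecipitation and sequencing (ChIP-seq). Per the labels, 2 libraries came from DNA precipitated with a rabbit polyclonal antibody to GFP (ab290) and 2 from input DNA, and replicate numbers 1 and 2 occur in each group. Per the labels' protocols, larvae were grown at 25 °C and cross-linked in 1.8% formaldehyde for 15 min. The labels do not say whether the replicates came from separate cultures, and the sex of the larvae is given as unknown.

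The submitters deposited 1 peak list for the whole series, and that list was the only measurement used here. Per the file headers, its coordinates are on FlyBase release 5 of the genome, and the list names MACS as the source of each peak. CASAVA 1.7.0.2, CASAVA 1.7.0.3, BWA and MACS2 are named in the submitters' processing notes, without their settings. Each peak has a first and last base (counted from 1) and a score, with no summit, fold enrichment or value per library. The score is the authors' deposited peak score. Which MACS statistic it is, its scale and the threshold used are not given in the sources used here, so scores were only ranked, summarised by medians and compared within this list. Whether the replicates were pooled before calling, called apart and joined, or filtered is not given either. Read depth per library is unknown, so a region without a peak is a region not called at an unknown depth, not a region shown to be unbound.

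The list holds 4198 peaks on 14 sequences, numbered without gaps. The lengths of the release 5 sequences were not used here. The length of each sequence was taken as the last base of its last peak, which is a lower bound and makes peaks per Mb an upper bound. Shares of the list carry exact (Clopper-Pearson) 95% binomial intervals, and peaks per Mb carry exact 95% Poisson intervals. Both cover counting error only and treat peaks as independent. Intervals of medians are exact binomial 95% intervals from order statistics. Spacing was tested against 1000 random placements of the same peaks, with their widths, on their own sequence, keeping at least 50 bp between peaks, which is the smallest gap in the list. The distance is from centre to centre, and the test is a two-sided permutation test whose smallest possible p is 0.002. Numbers of peaks on the X chromosome and the autosome arms were compared over full windows of 1 Mb, and median scores over peaks, with two-sided permutation tests of 100000 resamples. In all, 9 comparisons were adjusted together by the Benjamini-Hochberg method. They covered the number of peaks on the X, the median width on Uextra, and median scores. The scores were compared between sequences, between arm ends and the rest, and between peaks with and without a close neighbour. They were chosen after the list had been read, while the spacing test, the gene lists and the rule for named regions were fixed before the data were examined. Every p-value describes this 1 list and not the spread between animals or libraries. The tests of median scores and widths shuffled single peaks and treated neighbouring peaks as independent, so their p-values may be too small.

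The rule named the 10 peaks with the highest score and the 3 densest windows of 50 kb. The gene table used here is on release 6 of the genome, so no peak was assigned to a gene by position. The planned tests of transcription start sites, genomic class, gene lists (such as Notch pathway components, the E(spl) complex and the Hox genes), the binding motif of Su(H) and other motifs, and the Notch locus were therefore not run. The gene table served only for gene names and for which genes neighbour each other.

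The alternatives were the higher scored 2099 peaks, peaks within 1 kb of each other merged, the 5 large arms alone, windows of 20 kb with 3 peaks, and settings added after the data had been seen. The scripts were tested on simulated lists of 4198 peaks: of 20 lists with uniformly placed peaks 0 were called clustered, and of 20 lists with planted groups 20 were. For the X, counts per window of 1 Mb were simulated instead of lists, each drawn independently of its neighbours. An excess on the X was called in 0 of 20 simulations without a difference and in 20 of 20 with a ratio of 1.5. That ratio is above the observed 1.23, so these simulations do not give the power for the observed difference. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.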

Results

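Notch is a transmembrane receptor whose intracellular domain enters the nucleus on activation and acts there with the DNA-binding protein Su(H). To map the places on chromatin where the tagged receptor is found, GFP-tagged Notch was expressed from a transgene holding the Notch genomic coding region in larvae about to pupariate. Chromatin precipitated with an antibody to GFP (2 libraries) and input DNA (2 libraries) were sequenced. The result is available as 1 list of 4198 peaks called by the authors. The sources used here do not say how the input libraries entered the calling or which threshold was set. The list gives no value per replicate, so none of its peaks carries a replicate error. The labels give no precipitation from untagged larvae or with a control antibody. Signal that does not depend on tagged Notch could therefore not be told apart, and a peak here is a called region, not a proven Notch site.

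The peaks were narrow and together covered 2.57 Mb. Their median width was 481 bp (95% interval 472 to 495 bp), with quartiles of 323 and 764 bp, a minimum of 201 bp and a maximum of 4088 bp. The authors' score had a median of 26.1 (95% interval 24.9 to 27.3) and ran from 6.5 to 538.3. Scores were skewed: 578 peaks (13.8%) scored over 100, and the quartiles lay at 14.3 and 61.3. Wider peaks scored higher, with a Spearman rho of 0.738 and a Pearson r of 0.603 across the 4198 peaks, which are not independent replicates.

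The first question was how the peaks were spread over the chromosomes. All of the major arms carried peaks, and the 5 large arms held 3573 of them, 85.1% of the list (95% interval 84.0 to 86.2%). The X chromosome had 789 peaks (18.8% of the list), 3R had 788 (18.8%), 2R had 689 (16.4%), 2L had 658 (15.7%) and 3L had 649 (15.5%). Relative to length, the X had the most peaks of these arms, with 35.2 per Mb (95% interval 32.8 to 37.7). It was followed by 2R with 32.8 (30.4 to 35.4), whose interval overlaps that of the X. The other large arms carried fewer, with 28.6 per Mb on 2L (26.5 to 30.9), 28.3 on 3R (26.3 to 30.3) and 26.5 on 3L (24.5 to 28.6). The value for 2L includes a block of 87 peaks described below, 13.2% of the peaks on that arm. Its place above 3R and 3L rests on that block. In full windows of 1 Mb the X had 35.7 ± 13.0 peaks (SD over 22 windows) and the autosome arms had 29.1 ± 12.5 (SD over 94 windows). The ratio was 1.23 (95% bootstrap interval 1.02 to 1.45, permutation p = 0.03, adjusted p = 0.045 over 9 comparisons). Both the bootstrap and the permutation treated adjoining windows of an arm as independent, so they may understate the uncertainty. The call was lost when peaks within 10 kb of each other were merged (ratio 1.085, interval 0.952 to 1.23, permutation p = 0.182), and among the 2099 higher scored peaks the interval (0.993 to 1.40) included 1. Median scores on the X (24.4) and on the large autosome arms (25.4) were not told apart (permutation p = 0.523, same adjusted p of 0.523).

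**Figure D1:**
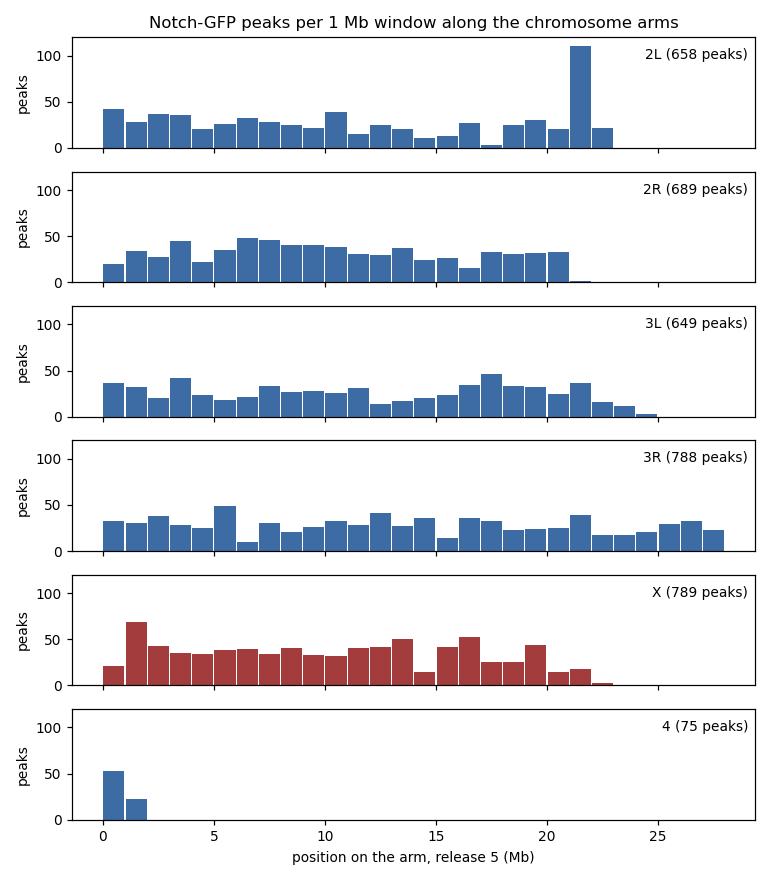
Number of Notch-GFP peaks (vertical axis) in each 1 Mb window along the 6 assembled chromosome arms (horizontal axis, position in Mb on release 5), with the X in red. The last window of each arm is shorter than 1 Mb. One window on 2L stands above all others, and the short chromosome 4 carries 75 peaks.

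The small chromosome 4, which is largely heterochromatic yet carries active genes, had the most peaks per Mb of the assembled arms and carried high-scoring peaks. Its 75 peaks came to 55.6 per Mb (95% interval 43.8 to 69.7), against 30.1 per Mb (29.1 to 31.1) over the 5 large arms together. They covered 4.73% of its length, against 1.90% on the large arms. Their median score was 53.8 (95% interval 35.8 to 128.0; n = 75 peaks), against 25.2 on the large arms (n = 3573 peaks; permutation p = 3.0e-05, adjusted p = 6.7e-05). Of the 75 peaks, 37 (49.3%) fell in the top 25% of all scores. Peaks on chromosome 4 were also wider, with a median of 763 bp against 498 bp on the large arms, and wider peaks scored higher across the list. The scores were not matched for width here, so how much of the difference goes with width is unknown.

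Sequence outside the assembled arms also held peaks. The 6 heterochromatic scaffolds, which are pieces of pericentromeric and Y chromosome sequence, carried 73 peaks at 8.71 per Mb (95% interval 6.82 to 10.9). Of these, 27 lay on 2RHet, 22 on 3LHet, 18 on 3RHet, 3 on XHet, 2 on 2LHet and 1 on YHet. Their pooled median score of 74.6 (95% interval 29.9 to 108.2) was above the 25.2 (24.0 to 26.6) of the large arms (n = 73 and 3573 peaks; permutation p = 1.0e-05, the smallest these permutations can give; adjusted p = 3.0e-05). The medians were 83.4 on 2RHet, 71.2 on 3LHet, 69.6 on 3RHet and 90.0 on 2LHet, but 15.4 on XHet and 24.9 on YHet, which were not above the large arms. Unmapped sequence strung together as U carried 38 peaks, with a median score of 47.1 (95% interval 28.5 to 79.3), which was not tested against the large arms. The lower-quality collection Uextra carried 439 peaks, 10.5% of the list (95% interval 9.55 to 11.4%). Peaks on Uextra had a median width of 371 bp, against 498 bp on the large arms (permutation p = 1.0e-05, the smallest possible; adjusted p = 3.0e-05). Their median score of 27.2 was not told apart from that of the large arms (permutation p = 0.259, adjusted p = 0.291).

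The highest-scoring regions were scattered over several arms. The peak with the highest score (538.3) lay on 2R from 15993550 to 15994696, and its nearest neighbour, 4.54 kb away, was the peak of rank 14, with a score of 323.0. The peak of rank 2, with a score of 441.6, lay on the scaffold 2RHet from 369614 to 370941. Rank 3 was a peak on 3R from 8889412 to 8890475 with a score of 403.3. Rank 4 was on 3LHet from 1396128 to 1397478, with a score of 367.2, and rank 5 was on 3L from 16044834 to 16046590, with a score of 364.1. The X carried ranks 6 to 8. These were the peaks from 16970508 to 16972201 (score 360.2), from 17720325 to 17721686 (score 358.5) and from 19530847 to 19532473 (score 353.4). Rank 9 lay on Uextra from 6918841 to 6919488 (score 349.1) and rank 10 on 2R from 942676 to 944057 (score 335.9). Among the 100 highest-scoring peaks, 25 were on the X (95% interval 16.9 to 34.7%), 9 on chromosome 4 (4.20 to 16.4%, against 1.79% of the whole list) and 6 on the heterochromatic scaffolds (2.23 to 12.6%, against 1.74%). The interval for the X includes its share of the whole list. Only 7 were on 2L (2.86 to 13.9%, against 15.7%), and 4 were on U (1.1 to 9.93%, against 0.905%). The share of 2L in the list includes a block of 87 peaks described below, 13.2% of the peaks on that arm. Peaks of the block scored at most 84.2, so none could be among these 100. The comparison for 2L without the block was not made. The intervals for 2R (16 peaks), 3L (12), 3R (15) and Uextra (6) included the shares of those sequences in the list.

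The next question was whether peaks came singly or in groups. They lay closer together than under uniform placement: the median distance from a peak to its nearest neighbour was 6.31 kb, against 12.9 kb in random placements (range 11.8 to 13.9 kb; permutation p = 0.002, the smallest possible). The placements were uniform over each sequence and made no allowance for gene density or mappable sequence. They therefore cannot tell grouping of Notch sites from an uneven spread of the sequence in which peaks can be called. On the 5 large arms 1722 of 3573 peaks (48.2%) had a neighbour closer than 5 kb. Over all sequences 182 windows of 50 kb held 5 or more peaks, against a median of 45 in random placements (range 27 to 63; permutation p = 0.002, the smallest possible). The median distance was shorter than in each of the 1000 random placements on all 5 large arms, from 4.37 kb on the X (random median 10.3 kb) to 6.58 kb on 3L (random median 13.5 kb). On chromosome 4 it was 4.38 kb against 6.83 kb (permutation p = 0.006), and the number of crowded windows there, 5 against a random median of 4, was not told apart from chance (permutation p = 0.466).

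**Figure D2:**
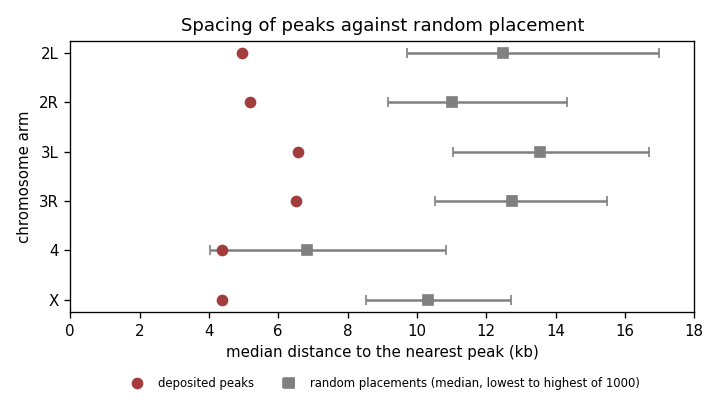
Median distance from a peak to its nearest neighbour in kb (horizontal axis) on each chromosome arm (vertical axis). Red points are the deposited peaks, and grey squares with bars give the median and the full range of 1000 random placements. The red points lie below the grey range on the 5 large arms and inside it on chromosome 4.

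The 3 densest windows of 50 kb adjoined each other on 2L. The window from 21450001 to 21500000 held 42 peaks, the one from 21500001 to 21550000 held 27, and the one from 21400001 to 21450000 held 18. The peaks covered 50.5%, 41.3% and 26.1% of these windows. Together they made 87 peaks between 21405851 and 21543548, 13.2% of the peaks on 2L and 2.07% of the list. The block held 22 peaks with scores from 50.9 to 84.2 and a median width of 1212 bp. Between and beside them lay 65 peaks with a median score of 15.0 and none above 28.2. Centres of the higher peaks were a median of 5062 bp apart, and 17 of their 21 intervals were within 10% of 5050 bp, the commonest spacing among all 87 peaks. The longest interval between higher peaks was 14.4 kb. Outside this block the most crowded windows, named after their values were seen, held 14 peaks (X, 12600001 to 12650000), 13 peaks (X, 1500001 to 1550000) and 12 peaks each (chromosome 4, 50001 to 100000; 3L, 17550001 to 17600000; 3R, 13500001 to 13550000).

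**Figure D3:**
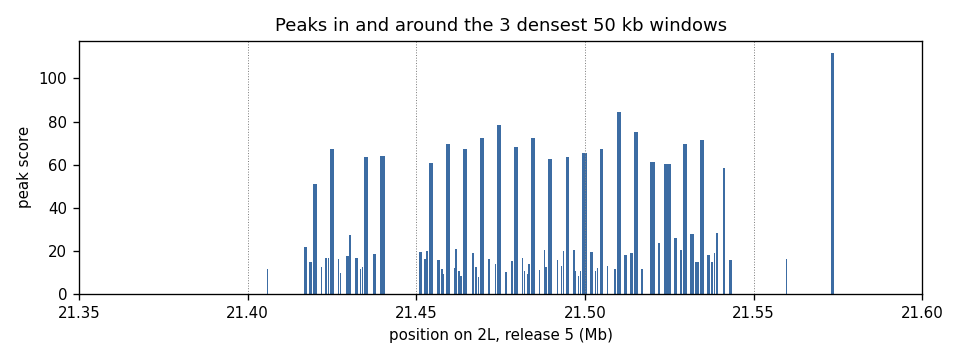
Peak score (vertical axis) against position on 2L in Mb on release 5 (horizontal axis). Each bar is 1 peak drawn at its own width, and dotted lines bound the 3 densest windows of 50 kb. Peaks with scores from 50.9 to 84.2 recur about every 5 kb between peaks with scores of 28.2 or less.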

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

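Of 45 values computed under alternatives, 30 kept their direction and their side of the threshold, stayed within their interval or, for the number of peaks, within 1.5 times of it, 14 moved, 1 lost its call and none reversed. All 9 alternative values for the spacing of peaks stayed on the clustered side (permutation p = 0.002 in each, the smallest possible). They included the 2099 higher scored peaks alone, merging within 1 kb and, added after the data were seen, omission of the 3 densest windows. The ratio of peaks per Mb between the X and the large autosome arms ranged from 1.085 to 1.29 over 7 alternatives, all added after the data were seen, with permutation p from 0.00102 to 0.182. The call was lost with peaks merged within 10 kb (ratio 1.085, permutation p = 0.182). The bootstrap interval also included 1 for the higher scored peaks alone (0.993 to 1.40) and for the highest scored 25% (0.992 to 1.54). Merging within 1 kb left 3566 regions of the 4198 peaks, with a median width of 537 bp and a median score of 30.4, against 481 bp and 26.1. The higher scored peaks numbered 2099 by construction, with a median width of 716 bp and a median score of 61.3. They had 2.53% of their number on chromosome 4 and 2.29% on the heterochromatic scaffolds, against 1.79% and 1.74% of the whole list. Merging within 1 kb put 14.5% of regions on 2L and 11.9% on Uextra, against 15.7% and 10.5%. Among the 5 large arms alone, where the total is smaller by construction, the shares were 18.4% on 2L, 19.3% on 2R, 18.2% on 3L, 22.1% on 3R and 22.1% on the X. The number of crowded windows depends on their definition, with 182 windows of 50 kb with 5 peaks and 355 windows of 20 kb with 3, and it was 28 for the higher scored peaks and 90 after merging. No paired analysis was possible because the list carries no value per replicate, and for the same reason no replicate could be left out. Other settings for transcription start sites, genomic class, gene lists, motifs and the Notch locus were not run, since their main tests were not. The depth of the libraries is unknown, so the number of peaks that deeper sequencing would add was not estimated.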

Other observations

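All tests in this part were run after the list had been read. Those on the repeated spacing and the histone genes were also chosen after their result was in view.

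Pooled over the large arms, peaks at the centromere end of the assembled sequence scored higher than those elsewhere. The heterochromatic scaffolds were not part of this comparison. In the Mb at that end, pooled over the 5 large arms, the median score was 57.8 (n = 97 peaks), against 24.8 in the rest (n = 3476; permutation p = 1.0e-05, the smallest possible; adjusted p = 3.0e-05). The test shuffled single peaks, while the contrast rests on 1 stretch of each of the 5 arms, so this p may overstate the evidence. The arms differed: the median was 164 on 3L from 8 peaks, 94.2 on 2L from 22, 66.6 on 2R from 20 and 45.5 on 3R from 33, but 16.7 on the X from 14. Leaving out any 1 arm kept the pooled median between 56.5 and 70.4. Peaks were also fewer at this end than in the arm without both end Mb. Per Mb there were 22 against 28.3 on 2L, 20 against 33.5 on 2R, 8 against 26.9 on 3L and 14 against 36.9 on the X. Only 3R went the other way, with 33 against 27.9. Whether a shortage of lower scored peaks raised the median was not tested. The Mb next to the telomere had a median of 30.3 (n = 164), against 24.9 elsewhere (permutation p = 0.0766, adjusted p = 0.0985).

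Peaks with a close neighbour scored lower than the other peaks of the large arms. Leaving out the 3 densest windows, peaks of the large arms with a neighbour under 5 kb away had a median score of 23.4 (n = 1636), against 28.0 for the others (n = 1850; permutation p = 1.1e-04, adjusted p = 2.0e-04). The groups were not matched for width, and weak peaks called beside stronger ones were not set apart.

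The block of 87 peaks on 2L has the spacing of a tandem repeat. At a spacing of 5050 bp it held 47 pairs of peaks, more than the highest count at any spacing in 1000 random placements within the block (33). This is consistent with copies of 1 unit, in which the same few positions are counted many times over and reads may be shared between copies. A candidate source is the histone gene cluster. In the gene order of the release 6 table, 2L has a run of 111 neighbouring histone genes, allowing 2 other genes between members. There were 23 copies each of His1, His2B and His3, 22 of His4 and 20 of His2A. It was the only run of 15 or more genes of 1 family on 2L. However, the histone types were joined into 1 family by a rule written for them, and other genes only by a shared name. Being the only such run is therefore no support for this candidate. No gene was placed on the release 5 coordinates, so the identity of the block stays a hypothesis, as does whether Notch is present there or the many copies distort the comparison with input. The block did not produce the grouping of the whole list, since without its windows the median distance to the nearest peak was 6.56 kb against 13.1 kb in random placements (permutation p = 0.002, the smallest possible).

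Any excess of peaks on the X stays open as to its cause. If weak peaks near the threshold made it, it should vanish among strong ones; among the highest scored 25% the ratio was 1.25 (permutation p = 0.0474), but its bootstrap interval of 0.992 to 1.54 included 1, so the test did not decide. If the X peaks were split into more close groups, merging within 10 kb should remove the excess. The ratio then was 1.085 (bootstrap interval 0.952 to 1.23, permutation p = 0.182), against 1.14 (95% range 1.094 to 1.187) after the same merging of 200 random placements at the observed densities. Random placements carry no grouping, while the peaks of every large arm are grouped, so this comparison does not decide whether the X is more grouped than the autosomes. Gene content of the X, its copy number in a mixture of the sexes and the amount of mappable sequence were not tested, and no biological explanation was tested.

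The high scores on the heterochromatic scaffolds are only partly narrowed down. Large-arm peaks drawn from the same width deciles had a median score of 32.9 (95% range of 10000 draws 24.7 to 43.2). This is 41.8 below the scaffolds' 74.6 (resampling p = 2.0e-04, from these draws and not from a permutation of labels). The draws take the scaffold median as fixed, and its own 95% interval of 29.9 to 108.2 includes 32.9. How much of the difference remains after matching for width is therefore uncertain. Per Mb the scaffolds held fewer peaks than the large arms (8.71 against 30.1) and fewer top 25% peaks (4.65 against 7.29, ratio 0.638, interval 0.451 to 0.880). Of the scaffold peaks 53.4% were in the top 25%, against 24.2% on the large arms. The high median thus went with a greater shortage of lower scored peaks and no surplus of strong ones. Whether missing weak peaks are the cause was not decided by the ratio. The low number of scaffold peaks limits it to 1.19 (lower bound 0.927) even if all 73 were in the top 25%. The lower quartiles of the scores were 14.7 on the scaffolds and 14.0 on the large arms. Reads from repeats that align to 1 assembled copy, and a real preference for such sequence, were not tested.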
